A study of Mus musculus with 10 samples.

How the data were processed

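RNA sequencing was done on microglia sorted from the cortex of 10 mice, 5 given LPS and 5 given saline, with 1 library per mouse. Per the labels' protocols, mice were perfused, the cortex was homogenised mechanically, leukocytes were enriched on a Percoll gradient, and cells with a high level of GFP were collected by flow cytometry. Per the labels' protocols, 5 ng of total RNA were amplified with a SMARTer ultra low input kit, and 6 ng of the product went into Ovation ultra low libraries. Amplified reads carry no molecular identifiers in these protocols, so counting intervals cover counting error only.

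The authors deposited a table of raw counts per gene; featureCounts and the builds GRCm38 and mm10 are named in the submitters' processing notes. The aligner, the version of the counter, the annotation and the use of strand are not given in the sources used here, so antisense and overlapping genes, paralogs and pseudogenes are uncertain. The authors also deposited 2 tables of normalised RPKM values, 1 mostly of protein-coding genes. Both carry the term CRAC in their names, which the sources used here do not explain. In both tables, each value was the count times 1 factor per library and 1 per gene. How these factors were chosen is not given in the sources used here. The count table listed 40789 genes, of which 13224 had no count in any library. Its last line, 1 row with no gene name and no counts, was left out. A spreadsheet had turned 15 gene names into dates, and these were named again from the Entrez gene ID. Of the gene IDs 37659 were found in a RefSeq table of GRCm38, from which biotypes and coordinates came.

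Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, the filterByExpr filter, and the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. No covariate entered the fit. Standard errors of log2 fold changes come from the log2 CPM of 5 and 5 libraries with a prior count of 2. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, beside camera with an estimated correlation and fry, for lists with at least 5 tested members. The 19 functional lists, 13 lists of other cells and 2 quality lists held 724 entries, of which 704 were matched. Mitochondrially encoded genes and some antigen receptor and globin genes were not analysed here. RPKM values were tested with limma on log2(RPKM + 1) for genes with a mean RPKM of at least 1. The spread between mice was the median over genes with a mean of at least 10 CPM of the absolute difference from the mean of the other mice of the group, compared by an exact two-sided permutation test. Summaries used Python 3.11.15 with scipy 1.17.1.

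Groups, tests, gene lists and alternatives were fixed before the data were examined. The rule for named genes took the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM and no overlap between groups. It added the 3 called members with the smallest adjusted p of each functional list, or the 2 with the highest mean where none was called, and the 2 members with the highest mean of each other list. Cx3cr1, P2ry12, Tmem119, Tlr4, Cd14, Il1b, Tnf, Il6 and Apoe were named in any case, and the text could leave out members named by lists. Some members of the lists are not reported here, and for that reason alone one of them was taken out of the monocyte sum after it had been computed; the sum was lower in LPS with it too. Gene groups, tests and alternatives that were chosen later are named as such. Alternatives were other scalings (RLE, upper quartile, library size only), no filter or a CPM filter, DESeq2 1.42.0, limma-voom, ranges of mouse numbers as a term, other pseudocounts and filters for RPKM, and each mouse left out. Protein-coding genes only and the removal of each library's gene-length trend were added after seeing the data; relative lengths came from the RPKM tables and covered 13199 genes.

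The tests were run on simulated counts with 200 genes changed. For LPS against saline, edgeR recovered 14.9% of genes changed 1.5-fold, 56.7% of those changed 2-fold and 80.3% of those changed 4-fold, with 4.72% of calls false, over 13150 genes. DESeq2 gave 17.9% false calls in the same simulation. With no change simulated, 0 genes and 0 lists were called. Genes were drawn independently there, while the estimated correlation was 0.46 for the interferon response list. The simulation therefore cannot show how often camera calls lists of correlated genes. The spread measure recovered a ratio of 1.90 where 2 was simulated. No pair of libraries of a group agreed within sampling noise: the chi-square per degree of freedom was at least 13.4.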

Results

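The series measured RNA from microglia, the resident macrophages of the brain, of 10 adult female mice. All carried 1 copy of the fractalkine receptor gene Cx3cr1 replaced by a green fluorescent reporter, and were 2 to 3 months old. Mice of the treated group (n = 5) received 4 mg/kg lipopolysaccharide (LPS), a bacterial cell wall component that activates innate immunity, into the peritoneum. Control mice (n = 5) received saline. Cells with high reporter fluorescence were sorted from the cortex 24 hours later, and each library came from 1 mouse. Total counts per library were 11577295 to 15274421 in saline and 12928007 to 15332121 in LPS (exact two-sided permutation p = 0.841 for the difference of means, n = 5 and 5). Values are CPM (counts scaled to library size with TMM factors) as mean ± SD over 5 mice per group, and log2 fold changes are LPS over saline with their standard error. Where a few members of a gene list are named without values, they were chosen after their values were seen.

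The design asks how microglial gene expression differs between mice given LPS and mice given saline. Cells sorted from LPS mice held much less RNA of the purinergic receptor gene P2ry12, a marker of resting microglia. They held more RNA of the scavenger receptor gene Msr1 and of interferon-induced genes. P2ry12 (Entrez gene 70839, chromosome 3, 59216271 to 59262985 on GRCm38) had 21585 ± 3362 CPM in saline and 2419 ± 1024.5 CPM in LPS, an 8.92-fold lower level (log2 fold change -3.16 ± 0.30, edgeR adjusted p = 8.12e-07). Msr1 (Entrez gene 20288, chromosome 8, 39543232 to 39642750), a macrophage scavenger receptor, went from 8.20 ± 2.32 to 818 ± 203 CPM (log2 fold change 6.64 ± 0.26, edgeR adjusted p = 2.04e-09). For both genes all 5 LPS mice lay on one side of all 5 saline mice. Of 13793 genes tested with edgeR, 3093 were called higher and 3110 lower in LPS, and the change was at least 2-fold for 1432 and 1370 of them. The groups did not overlap for 4112 genes, or 29.8% of those tested, where chance gives 0.794%.

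**Figure D1:**
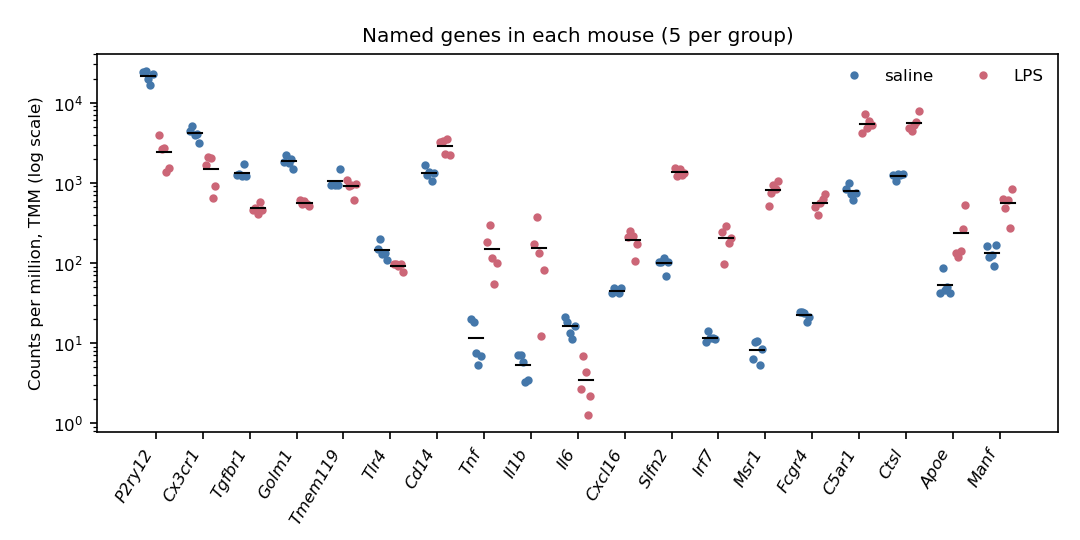
CPM (TMM factors, log axis) of 19 named genes in each mouse; blue points are the 5 saline mice, red points the 5 LPS mice, and black lines are group means. P2ry12 had a mean of 21585 CPM in saline and 2419 CPM in LPS, while Tmem119 overlapped between the groups.

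The 10 largest rises were ranked among called genes with a mean of at least 5 CPM over the 10 libraries and no overlap between the groups. Lcn2, which encodes a protein that binds bacterial iron carriers, rose from 0.762 ± 0.580 to 233 ± 213 CPM (edgeR adjusted p = 6.48e-06). Saa3, an acute phase apolipoprotein, rose from 1.02 ± 0.874 to 220 ± 195 CPM, and Il1r2, the decoy receptor for interleukin 1, from 18.6 ± 14.4 to 4094 ± 3060 CPM. Plet1 (262 ± 225 CPM in LPS), Tarm1 (15.1 ± 8.16), Fn1 (34.4 ± 11.1), Trem1 (106 ± 105), Inf2 (20.6 ± 19.7) and Adamtsl4 (76.5 ± 45.3) complete the list with Lrg1. Lrg1 had 2 raw counts over the saline libraries, both in replicate 2, and 1090 over the LPS libraries, a ratio of 570 with a 95% counting interval of 157 to 4710; without that mouse no saline count was left. The edgeR adjusted p of these 10 genes were between 2.48e-08 (Fn1) and 4.35e-05 (Inf2). The fold of Lcn2 was 314 with all mice and 205 without LPS replicate 5, that of Saa3 225 and 143 without the same mouse, that of Trem1 174 and 99.96 without LPS replicate 4, and that of Inf2 164 and 259.8 without saline replicate 3.

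The 10 largest falls, ranked with the same limits, lay between 15.1-fold (Klhl23) and 41.7-fold (Duoxa1). Upk1b fell from 474 ± 92.5 to 24.8 ± 13.9 CPM (log2 fold change -4.26 ± 0.34, edgeR adjusted p = 3.03e-07). Kcnma1, a calcium-activated potassium channel, had 11.01 ± 1.51 CPM in saline and 0.707 ± 0.248 CPM in LPS. Hlf, a transcription factor of the circadian output, had 12.5 ± 2.36 and 0.742 ± 0.243 CPM. Klhl23 (1.72 ± 0.512 CPM in LPS), Gm30789 (0.778 ± 0.390), Ptchd1 (0.802 ± 0.685), Gprasp2 (0.677 ± 0.794), Duoxa1 (0.231 ± 0.257), Adamts16 (0.667 ± 0.590) and Cdhr4 (0.645 ± 0.252) were the others. The fold of Duoxa1 was 72.2 without LPS replicate 1, that of Gprasp2 31.2 and 59.6 without the same mouse, and that of Ptchd1 38.2 and 57.9 without LPS replicate 2.

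Genes of homeostatic microglia fell as a group. Of 32 tested members, 21 fell and 1 rose, and 21 and 2 adjusted over the list alone (camera adjusted p = 1.97e-07, and adjusted p = 0.175 with an estimated correlation). Golm1 fell 3.32-fold from 1859 ± 264 CPM, Rasgrp3 fell 3.64-fold from 463 ± 47.7 CPM, and Cx3cr1, the locus that carries the reporter, fell 2.80-fold from 4134 ± 736 CPM (edgeR adjusted p = 0.000819). The member that rose was P2ry6, named here after its values were seen, a receptor for uridine nucleotides that promotes phagocytosis (713 ± 88.1 and 1513 ± 304 CPM). Tmem119, a microglial surface marker, had 1058 ± 246 CPM in saline and 899 ± 179 CPM in LPS (edgeR adjusted p = 0.302). Over 18 alternative settings its adjusted p lay between 0.123 and 0.691, and with a trend over gene length removed from each library it was called lower (log2 fold change -0.44, edgeR adjusted p = 0.0464).

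Among 16 tested genes of TGF-beta signalling, a pathway that maintains microglial identity, 7 fell and 1, Tgif1, rose, with the same numbers adjusted over the list alone (camera adjusted p = 0.0337). The list had an adjusted p = 0.175 with an estimated correlation, and 0.00968 to 0.0425 over 15 other settings of camera. The estimated correlation itself was 0.00597, below the preset 0.01, so stronger correlation between members does not account for the higher p. With the gene-length trend removed the call ended (adjusted p = 0.380), the median log2 fold change going from -0.45 (SD over members 0.61) to -0.14 (0.58). Tgfbr1, the type 1 receptor, fell 2.80-fold from 1339 ± 223 to 478 ± 63.8 CPM. Eng, a co-receptor, fell 2.76-fold from 27.2 ± 9.24 CPM, and Bmpr2 fell 2.00-fold from 92.5 ± 7.28 CPM.

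Cytokine and chemokine genes were higher in LPS for 15 of 24 tested members and lower for 2, and for 17 and 2 adjusted over the list alone (camera adjusted p = 0.000544, and adjusted p = 0.229 with an estimated correlation). Tnf rose 12.85-fold to 149 ± 93.5 CPM (edgeR adjusted p = 3.35e-05). Il1b rose 29.0-fold to 155 ± 138 CPM, and 18.7-fold without LPS replicate 2. The chemokine genes Cxcl16 and Cxcl13 rose 4.24-fold and 38.1-fold. Ccl5 rose 111-fold to 470 ± 662 CPM, and 41.8-fold without LPS replicate 5. The falling members were Ccl6 and Il6, and Il6, an acute phase cytokine, fell 4.65-fold from 16.1 ± 4.04 CPM (edgeR adjusted p = 0.000262).

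Of 34 tested genes of TLR4 and NF-kB signalling, through which cells sense LPS, 18 rose and 3 fell, and 19 and 3 adjusted over the list alone (camera adjusted p = 9.83e-05, and adjusted p = 0.175 with an estimated correlation). Cd14, the LPS co-receptor, rose 2.18-fold to 2902 ± 606 CPM, while Tlr4 itself fell 1.55-fold from 143 ± 33.3 CPM (edgeR adjusted p = 0.00513). Nfkb1 and Traf6 were the other members that fell. The feedback regulators Socs3 and Bcl3 rose to 139 ± 13.9 and 11.2 ± 3.03 CPM, and the kinase gene Map3k8 rose 4.69-fold. The 41.1-fold rise of Bcl3 was 67.5-fold without saline replicate 3.

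The interferon response list had the smallest list p with camera at the preset correlation, but not with fry. Of 41 tested members 38 rose and none fell, with the same numbers adjusted over the list alone (camera adjusted p = 1.05e-18, and adjusted p = 0.175 with an estimated correlation). Slfn2 rose 13.8-fold to 1366 ± 136 CPM, the DNA sensor gene Ifi204 41.6-fold to 224 ± 58.9 CPM, and Irf7, a regulator of type I interferon, 17.4-fold to 202 ± 71.2 CPM. Genes of MHC class I presentation rose for 16 of 19 tested members and fell for none, also adjusted over the list alone (camera adjusted p = 2.40e-06, and adjusted p = 0.175 with an estimated correlation). Examples were the transactivator Nlrc5 (8.54-fold), H2-T23 (3.10-fold) and the proteasome activator Psme1 (2.93-fold). The MHC class II and costimulation list split, with 4 of 14 members higher and 5 lower, or 5 and 5 adjusted over the list alone (camera adjusted p = 0.667). Cd74, the invariant chain, rose 4.11-fold and Cd40 9.53-fold, and Ctss and H2-DMb1 also rose. H2-Ob, which modulates peptide loading, fell from 102 ± 4.25 to 24.4 ± 6.02 CPM, and H2-Eb1, H2-Aa, H2-Oa and Cd80 also fell.

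Complement and phagocytic receptor genes rose for 19 of 25 tested members and fell for 4, with the same numbers adjusted over the list alone (camera adjusted p = 6.27e-06, and adjusted p = 0.175 with an estimated correlation). Besides Msr1, the Fc receptor gene Fcgr4 rose 25.0-fold to 562 ± 125 CPM and C4b 42.0-fold to 62.9 ± 15.04 CPM, while Mertk, Trem2 and Itgam were among those that fell. Of 24 tested disease-associated microglia genes, 13 rose and 5 (Timp2, Cd9, Ctsd, Trem2 and Ccl6) fell, also adjusted over the list alone. The list was not called (camera adjusted p = 0.0501, and adjusted p = 0.243 with an estimated correlation), but was in 10 of 15 other settings of camera (adjusted p of 0.0162 to 0.0654), and not with the gene-length trend removed (adjusted p = 0.281, the median log2 fold change going from 0.82 to 0.44). Among the 10 were the fits without saline replicates 1, 3 and 4 (0.0346, 0.0435 and 0.0466) and without LPS replicates 2, 3, 4 and 5 (0.0310, 0.0484, 0.0379 and 0.0314). Fry called this list higher (fry adjusted p = 0.000175). Spp1 rose 40.8-fold to 174 ± 115 CPM, Cd63 6.09-fold to 871 ± 258 CPM, and the lipid carrier gene Apoe 4.44-fold to 238 ± 175 CPM.

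Genes of the unfolded protein response rose for 17 of 20 tested members and fell for none, also adjusted over the list alone (camera adjusted p = 6.49e-06, and adjusted p = 0.182 with an estimated correlation). Manf and Creld2, secreted on stress of the endoplasmic reticulum, rose 4.25-fold and 2.91-fold, and the chaperone gene Dnajb11 2.54-fold. Migration and adhesion genes rose for 15 of 27 members and fell for 5, and for 17 and 6 adjusted over the list alone (camera adjusted p = 0.0196, and adjusted p = 0.182 with an estimated correlation). Ccr2, Msn, Itgam and Itgb1 were among those that fell. C5ar1, the receptor for complement C5a, rose 7.02-fold to 5470 ± 1182 CPM, Gpr84 7.73-fold and the integrin gene Itga5 2.52-fold. Of 10 tested alternative activation genes 5 rose and none fell, with 6 higher adjusted over the list alone (camera adjusted p = 0.0184, and adjusted p = 0.175 with an estimated correlation), namely Msr1, Socs3, Stab1, Il1rn and Il4ra. The estimated correlation of the alternative activation list was -0.0439, also below the preset 0.01. Il4ra, a receptor chain for interleukin 4, rose 2.49-fold. Of the 18 listed alternative activation genes 10 also stand in another list, Msr1 and Socs3 among them. The call of Stab1 depended on the setting, as given below. Mrc1 was not among the genes that rose (mean 10.3 CPM in saline, 7.32 in LPS).

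Ribosomal protein genes rose for 37 of 44 tested members and fell for none, and 41 adjusted over the list alone (camera adjusted p = 1.57e-13, and adjusted p = 0.189 with an estimated correlation). Rpl14 rose 3.39-fold, Rps18 3.54-fold and Rpl18 2.87-fold. Oxidative phosphorylation genes rose for 27 of 35 members and fell for 2, and for 28 and 2 adjusted over the list alone (camera adjusted p = 6.27e-06, and adjusted p = 0.351 with an estimated correlation). The falling members were Sdha and Ndufs1. Atp5b rose 1.78-fold, Cox4i1 2.08-fold and Uqcrq 2.68-fold. Short genes were higher in LPS libraries as a whole: of 5 equal groups of genes by length, the shortest held 14.8% ± 2.23 (SD, n = 5) of counts in saline and 23.4% ± 3.56 (SD, n = 5) in LPS (exact two-sided permutation p = 0.00794, the smallest that 5 against 5 mice can give). With that length trend removed from each library, an alternative chosen after the data were seen, 26 ribosomal protein genes rose and none fell (camera adjusted p = 8.95e-09), while 8 oxidative phosphorylation genes rose and 3 fell (camera adjusted p = 0.0743). Pseudogenes followed the same trend, with 345 called higher and 50 lower; their counts are uncertain where reads match a parent gene.

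**Figure D2:**
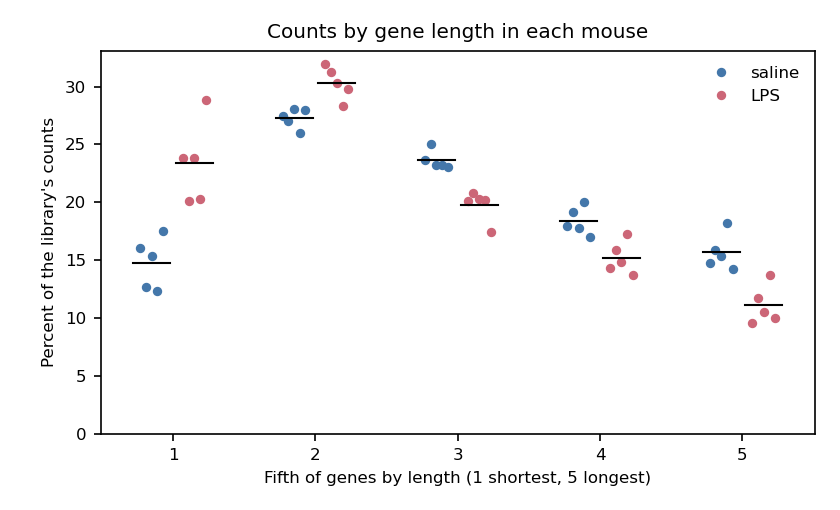
Percent of each library's counts (vertical axis) in 5 equal groups of genes ordered by length (horizontal axis, 1 shortest); blue points are 5 saline mice, red points 5 LPS mice, and black lines are means. The group of shortest genes held 14.8% of counts in saline and 23.4% in LPS on average.

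The other functional lists were not called with camera at the preset correlation. Fry, which does not compare members with other genes, called 3 of them higher. These were lysosome (fry adjusted p = 2.96e-05), cholesterol (0.000175) and glycolysis (0.00334), but not cell cycle (0.0914) or immediate early genes (0.325). Glycolysis genes rose for 6 of 18 members and fell for 3, or 6 and 4 adjusted over the list alone (camera adjusted p = 0.198), with Pkm 2.01-fold, Gpi1 1.97-fold and Ldha 1.84-fold higher and Pfkm, Hk3 and Hif1a lower. Lysosome genes rose for 12 of 30 and fell for 8 (camera adjusted p = 0.137), also adjusted over the list alone, and the protease genes Ctsl, Ctsc and Ctsh rose 4.62-fold, 4.03-fold and 2.79-fold. Cholesterol genes rose for 8 of 23 and fell for 3, also adjusted over the list alone (camera adjusted p = 0.121, 0.0832 to 0.203 over 15 other settings, and 0.0382 with the gene-length trend removed). Mvd and Insig1 rose 4.38-fold and 2.15-fold, and Hmgcs1 and Mylip were among those that fell. Cell cycle genes rose for 7 of 24 and fell for none, also adjusted over the list alone (camera adjusted p = 0.138), with the cycle inhibitor Cdkn1a 7.88-fold and Mcm7 1.61-fold higher. The 1.66-fold rise of Pcna (edgeR adjusted p = 0.00280, and 0.000178 to 0.00866 over 18 other settings) was not called with the length trend removed (log2 fold change 0.24, edgeR adjusted p = 0.242). Immediate early and dissociation-linked genes rose for 7 of 24 members and fell for none, with 6 higher adjusted over the list alone (camera adjusted p = 0.167, and 0.0255 to 0.641 over 15 other settings, the lowest without saline replicate 1). Among them were Ier3 (10.3-fold), Hspa8 (2.47-fold) and Klf6 (1.64-fold).

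**Figure D3:**
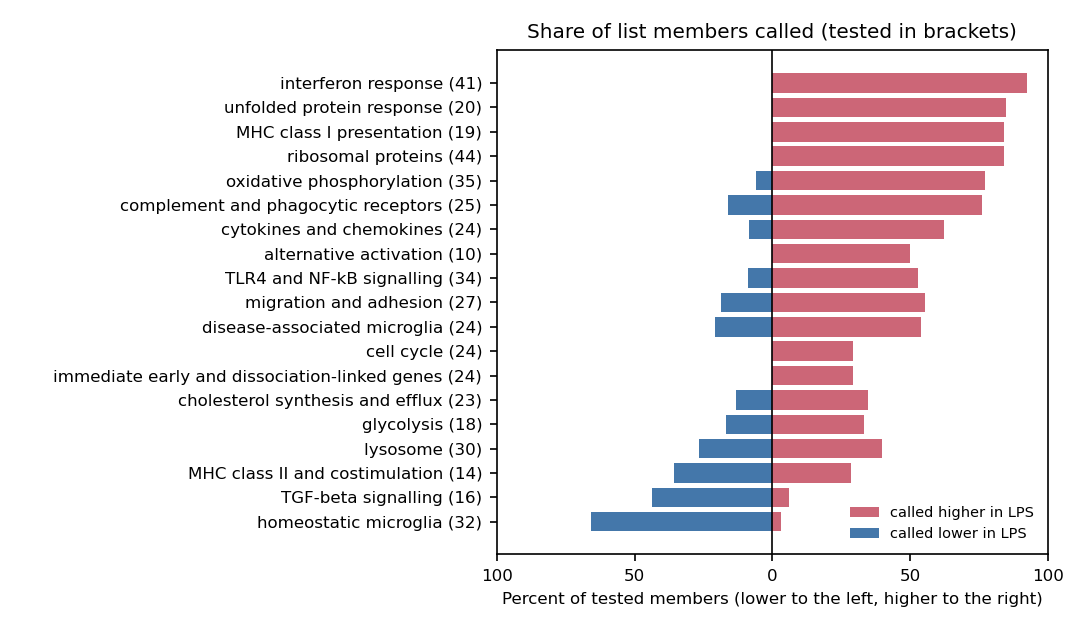
Percent of tested members of each functional gene list that were called higher (red, right) or lower (blue, left) in LPS against saline, with the number of tested members in brackets. The interferon response list had 38 of 41 members higher, and the homeostatic microglia list 21 of 32 lower.

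Markers of other cells moved in both directions. Of the monocyte list 3 of 9 tested genes (Fn1, Ms4a4c and F13a1) rose and 2 (Ccr2 and Spn) fell, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.212; median log2 fold change -0.20, mean 1.33, direction of the test higher), with Ms4a4c 23.7-fold higher. Fry called the monocyte list higher (fry adjusted p = 0.000649). Ccr2, a receptor that draws monocytes to tissue, named after its values were seen, fell from 10.2 ± 2.93 to 2.45 ± 1.54 CPM. Border-associated macrophage genes rose for 5 of 8 tested members (Siglec1, Dab2, F13a1, Cbr2 and Stab1) and fell for none, also adjusted over the list alone (camera adjusted p = 0.0130, and adjusted p = 0.175 with an estimated correlation). Dab2 rose 5.52-fold to 141 ± 45.6 CPM; Stab1 rose 1.54-fold (edgeR adjusted p = 0.0390). That call was lost without LPS replicate 4 (log2 fold change 0.33, edgeR adjusted p = 0.0817), without saline replicates 1, 2, 3 or 5 (adjusted p of 0.0951, 0.0665, 0.0689 and 0.0796), and with library size alone, limma-voom or a term for ranges of mouse numbers (0.0843, 0.0545 and 0.0776). Of 3 tested neutrophil genes Lcn2 and Cxcr2 rose and Csf3r, which microglia also express, fell 1.67-fold from 668 ± 87.8 CPM, with the same calls adjusted over the list alone. With no count filter 13 members were tested and the list was called higher (camera adjusted p = 0.0165).

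Tested lymphoid, neural and vascular markers fell or were not called. Few listed genes had a mean of at least 1 CPM in saline: 3 of 15 endothelial, 2 of 13 T cell and 1 of 12 NK cell genes. For B cells it was 2 of 9, for neurons 3 of 14 and for astrocytes 5 of 13. Cldn5 of the endothelial list had 0 raw counts in saline and 0 in LPS. The falls given here therefore do not show a loss of such cells, and which cells held this RNA was not tested. Il7r of the T cell list fell 5.50-fold from 67.8 ± 9.41 CPM, and Klrd1 of the NK cell list had 393 raw counts in saline and 3 in LPS, a ratio of 125 with a 95% counting interval of 42.6 to 610.3. Each was the 1 tested member of its list and was also called adjusted over the list alone. Of 2 tested B cell genes Cd22 fell 2.42-fold, while Cd79b had 96.8 ± 16.3 and 93.1 ± 28.7 CPM (edgeR adjusted p = 0.821, 0.220 to 0.999 over 18 other settings, and 0.00226 with the length trend removed, log2 fold change -0.58). Of 3 endothelial genes 3 fell, Vwf, Pecam1 (7.63-fold from 54.1 ± 10.3 CPM) and Kdr (2.47-fold). With no count filter 14 endothelial genes were tested and the list was called lower (camera adjusted p = 0.0239). Slc1a3 of 8 tested astrocyte genes fell 1.81-fold (camera adjusted p = 0.781; median log2 fold change -0.18, mean 0.06), and Aldoc had 16.8 ± 3.499 and 20.02 ± 7.11 CPM. Of 2 neuronal genes Camk2a fell 5.80-fold and Snap25 had 4.77 ± 1.18 and 3.82 ± 1.52 CPM. None of 5 oligodendrocyte genes was called (camera adjusted p = 0.566); Mbp had 39.6 ± 10.5 and 31.2 ± 9.61 CPM, with an edgeR adjusted p = 0.204 and 0.0446 to 0.437 over 18 other settings, the lowest, which called it lower, without LPS replicate 2. Cnp, Acta2 of pericytes, and Hbb-bs and Alas2 of erythrocytes were not called either. Adjusted over each list alone, these B cell, endothelial, astrocyte and neuronal counts were the same. No oligodendrocyte precursor or Y-linked gene passed the count filter.

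The series title names individual mice, so the spread between mice of a group was compared. The median distance of a mouse from the other mice of its group was 0.193 ± 0.0537 (SD, n = 5) on the log2 scale in saline and 0.248 ± 0.0645 (SD, n = 5) in LPS. The difference was 0.0549 (exact two-sided permutation p = 0.183), which does not settle whether the groups differ in spread. Distances within a group share mice and so are not independent, which makes the permutation p values here only approximate. The difference was 0.0913 without LPS replicate 3 (exact p = 0.0397), 0.0260 without saline replicate 3 (exact p = 0.508) and 0.0252 without LPS replicate 4 (exact p = 0.540). With the gene-length trend removed it was 0.0540 (exact p = 0.0397). The first principal component held 56.2% of the variance and separated the groups, and the second held 14.7%, with LPS replicate 4 at -78.1 and the other LPS mice between -0.633 and 36.3.

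**Figure D4:**
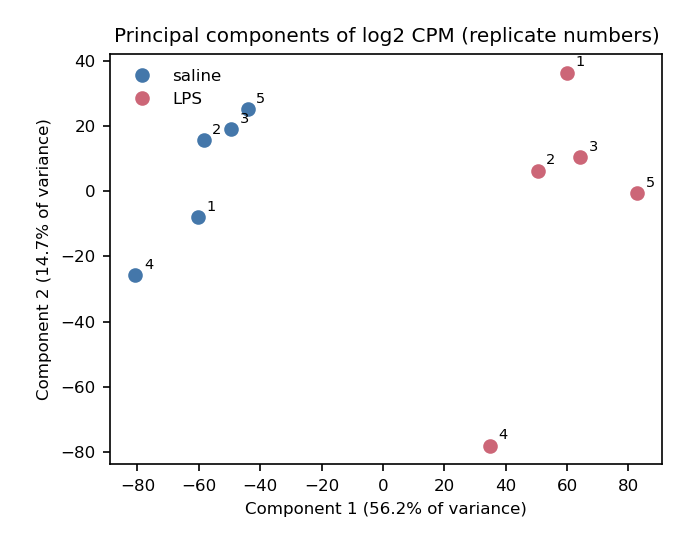
First (horizontal) and second (vertical) principal components of log2 CPM over 13793 genes; blue points are saline mice, red points LPS mice, and numbers are replicates. The first component, with 56.2% of the variance, separates the groups, and LPS replicate 4 lies at -78.1 on the second.

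In the authors' normalised RPKM table, tested with limma on log2(RPKM + 1), 3145 genes were higher and 2535 lower in LPS among 11147 with a mean RPKM of at least 1. Of these, 5324 were also called in the counts, all in the same direction. The table holds the same reads as the counts, so it is no independent measurement. With a mean RPKM of at least 5, the genes called lower were 1489, among 6826 tested.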

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

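All tests of explanations in this part were chosen after the results were seen. Within each group of 5 mice, 258 sets of values were checked for a mouse far from the rest, and 21 were found. The nominal rate of 1 in 20 would give 12.9. That rate holds for normally distributed values, while most sets were CPM not on a log scale, and all sets share the same mice. The excess over 12.9 therefore does not show more outliers than chance.

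LPS replicate 4 stood apart in 5 of them. It had 40.3 CPM of Creld2 (others at least 88.5), 207 of Ldha (others at least 294), 5.83 of Eng (others at least 9.94), 1842 of Stab1 (others at most 1005), and a mean log2 CPM of 7.498 over the unfolded protein response list (others at least 8.11). Its distance from the other LPS mice was 0.340 (others 0.169 to 0.279). It was 0.343 with all libraries thinned to the smallest total (others at most 0.278) and 0.270 with the gene-length trend removed (others at most 0.225), so neither depth nor that trend accounts for all of it. A saline mouse labelled LPS would lie among the saline mice on the first principal component, but this mouse lay at 35.02 and the saline mice at most at -44.1. It had the lowest P2ry12 of all mice (1367 CPM), the lowest mean log2 CPM of the homeostatic microglia list (9.08) and the highest Trem1 (285 CPM), so its response to LPS was not weaker in all genes. Saline replicate 4 deviated from its own group in a similar way. The deviations of these mice from their group means had a correlation of 0.54, the highest of any pair of a saline and an LPS mouse. On the second principal component saline replicate 4 lay at -25.9, and the other saline mice at -8.07 to 25.1. What set LPS replicate 4 apart stays open, and a response at another time was not tested.

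LPS replicate 5 had the highest Ccl5 (1651 CPM, others at most 224) and Cd74 (1240 CPM, others at most 838). It had the lowest C4b (36.8 CPM, others at least 63.5) and Tlr4 (76.5 CPM). Saline replicate 2 had the highest Pecam1 (72.0 CPM), Apoe (87.3 CPM) and Lrg1 (0.170 CPM, others 0) and the lowest Ctsl (1042 CPM) of the saline mice. Saline replicate 1 had the highest Socs3 (32.3 CPM) and Pcna (22.9 CPM). Saline replicate 3 had the highest Bcl3 (0.727 CPM). Saline replicate 4 had the highest Gm30789 (23.6 CPM) and Tgfbr1 (1734 CPM). Saline replicate 5 had the highest Tmem119 (1499 CPM), the lowest mean log2 CPM of the MHC class II and costimulation list (5.80) and the highest of the unfolded protein response list (7.195).

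Short genes were higher in LPS, with a median log2 fold change of 0.70 in the group of shortest genes and -0.46 in the longest. A few genes taking most of the counts do not account for it: the 10 most abundant genes of a library held 14.8 ± 0.741% of counts in saline and 12.5 ± 0.456% in LPS, which shifts all other genes by a log2 of 0.039 (at most 0.0563 between an LPS and a saline library). Removing the trend took the oxidative phosphorylation list from a median of 0.81 (SD over members 0.43) to 0.25 (0.33), ending its call as the folds shrank, and the calls among 1013 pseudogenes with a length (of 1195 tested) from 318 higher and 47 lower to 93 and 95. It may account for these, but not for all of the ribosomal protein rise, where the median went from 1.17 (SD 0.41) to 0.56 (0.38) and the list was still called. Reads shared with parent genes cannot be told apart from this trend, as only 94 pseudogenes (7.87%) had a named parent (Spearman correlation of log2 fold changes 0.71 across these genes, which are not independent replicates), and neither can RNA quality or library making from the LPS response, as the share of counts in the shortest genes differed by 8.59 percentage points with no overlap between groups.

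Genes of other myeloid cells were among the largest rises, and a candidate source is cells other than microglia in the sort, which took cells with high GFP (7 of 18 monocyte, 1 of 16 neutrophil and 6 of 16 border macrophage genes had at least 1 CPM in saline, and 4, 1 and 4 stand in another list). The summed level of Ly6c2, Ccr2, Plac8, Vcan, S100a4 and S100a6, abundant in monocytes, was 3.12 CPM lower in LPS (sum 13.2 ± 3.91 in saline, 10.1 ± 5.79 in LPS, change -3.12, and -4.84 to -1.88 with 1 mouse left out) while Fn1, F13a1 and Ms4a4c together rose by 136 CPM. The lower monocyte sum came mostly from Ccr2 (mean 10.2 CPM in saline, 2.45 in LPS), and S100a4 was also lower. Plac8 was higher (2.28 CPM in saline, 6.65 in LPS), as were Ly6c2, Vcan and S100a6, so the direction of the sum rests on Ccr2. S100a8, S100a9, Ngp, Camp and Retnlg of neutrophils rose by 6.16 CPM together (S100a8 to 3.52 ± 4.00 CPM) against 232 CPM for Lcn2. LPS replicate 4 held 19.8 CPM of these markers and the other LPS mice 0.538 to 9.08, and without it the rise was 2.81 CPM, against 214 CPM for Lcn2. Mrc1, Cd163, Lyve1 and Pf4 of border macrophages changed by -3.25 CPM together, against 147 CPM for F13a1, Cbr2, Siglec1 and Dab2. Most of that change was Mrc1 (mean 10.3 CPM in saline, 7.32 in LPS). The marker sums changed by far less than these rises, so cells that keep these markers abundant do not account for them. Such sums cannot exclude cells that lose these markers under LPS. The neutrophil sum and Plac8 leave room for a trace of neutrophils or monocytes in LPS. Induction within microglia stays open as a hypothesis.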

How the results depend on the processing

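The gene-length trend removal, the test of protein-coding genes only and the bounds for other splits of the mice were chosen after seeing the data. Counts of calls kept within 1.5 times under every alternative of the count test other than the removal of the length trend: leaving out 1 mouse gave 2661 to 3607 genes higher and 2657 to 3559 lower, DESeq2 gave 3728 and 3327, library size alone 2656 and 3482, and ranges of mouse numbers as a term 2798 and 2904 (deviations of libraries from their group mean had a median correlation of 0.0714 over 8 pairs of the same range and 0.0302 over 17 pairs of different ranges). No called gene was called in the opposite direction under any alternative of the count test. With the length trend removed, 953 genes were called higher by at least 2-fold; 3964 of the calls remained with their direction, and 1 list was called lower. Camera with an estimated correlation called 0 lists higher and 0 lower (5 lists had an unadjusted p under 0.05), where fry called 16 and 2, and camera without 1 mouse 11 to 13 higher and 2 lower. No paired analysis was possible because the labels number each mouse once and the groups share no number. Requiring a mean RPKM of at least 5 left 1489 genes lower, with fewer genes tested. The difference in spread was 0.0252 to 0.0913 with 1 mouse left out and 0.0540 with the length trend removed; the cause was not tested. Among 101 named genes none that was called changed sign; Stab1 lost its call under 8 alternatives and Pcna with the length trend removed. Of the genes not called 5 changed sign around 0: Cnp with log2 fold changes of 0.045 without saline replicate 2, 0.0172 without saline replicate 5, 0.0231 and 0.0944 without LPS replicates 2 and 4 (range -0.118 to 0.0944 with 1 mouse left out), and 0.000671 among protein-coding genes; Alas2 with 0.19 without saline replicate 1 and 0.13, 0.16 and 0.03 without LPS replicates 2, 3 and 5 (range -0.73 to 0.19); Acta2 with -0.041 in limma-voom and -0.00712 without LPS replicate 5 (range -0.00712 to 0.48); Cd79b with 0.00794 and 0.0157 without LPS replicates 3 and 4 (range -0.25 to 0.0157); and Mbp with 0.0751 with the length trend removed. Of 100 splits of the 10 mice, the real one included, 1 gave as many called genes (6203, at most 883 in the others). For 2-fold changes 1 split gave as many (2802, at most 427), and 1 in the RPKM table (5680, at most 1793). Every other split mixed LPS and saline mice, which adds the treatment difference to the spread within each side. Fewer calls in those splits therefore do not exclude chance. For gene lists 5 of the 100 splits gave at least 13, and the highest other gave 14. The others that gave at least 13 kept 4 mice of 1 treatment on the same side, so much of the treatment difference remained in them. These splits therefore cannot decide how many lists chance would give. Depth limits genes near the count filter. A 1.5-fold change was recovered for 14.9% of simulated genes, but far fewer genes were changed there than the 6203 called here. The Benjamini-Hochberg cutoff was therefore stricter in the simulation, so that share does not give the recovery of 1.5-fold changes in these data.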

Other observations

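The gene groups in this part were chosen after the data were seen, and no explanation was tested for them. Of 17 clock genes tested, 8 were lower and 2 higher in LPS. Tef fell from 64.7 ± 21.7 to 5.67 ± 0.718 CPM (log2 fold change -3.51 ± 0.22), Nr1d1 from 28.8 ± 13.7 to 2.23 ± 0.913 CPM (-3.68 ± 0.42), and Per3 from 43.5 ± 15.3 to 9.02 ± 2.30 CPM (-2.27 ± 0.29). Nfil3, which represses the targets of the Tef and Hlf family, rose from 2.85 ± 1.501 to 24.8 ± 23.1 CPM, with 65.7 CPM in LPS replicate 4 and 8.87 to 18.2 in the other LPS mice. Arntl had 9.30 ± 1.84 and 8.55 ± 1.88 CPM (edgeR adjusted p = 0.655). The labels used here give 24 hours between injection and sampling and no time of day.

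Of 8 genes of iron handling 6 rose and 1 fell. The ferritin genes Fth1 and Ftl1 rose 5.04-fold and 2.02-fold, to 4368 ± 1880 and 626 ± 160 CPM, and the iron exporter gene Slc40a1 fell 5.05-fold from 674 ± 137 CPM. Of 7 pentose phosphate pathway genes 4 rose and none fell, with Pgd 2.12-fold and Taldo1 2.03-fold higher. Of 7 Ms4a family genes 6 rose: Ms4a4a from 4.77 ± 2.21 to 587 ± 524 CPM, and Ms4a6d from 268 ± 48.6 to 3010 ± 1054 CPM.

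Of 11 tested genes that respond to glucocorticoids, 8 rose and 2 fell, with a wide spread among LPS mice. LPS replicate 4 had the highest level of Fkbp5 (428 CPM, against 60.5 to 207 in the other LPS mice) and of Tsc22d3 (2434 CPM, against 155 to 619). The glucocorticoid receptor gene Nr3c1 fell 1.95-fold from 219 ± 17.5 CPM (edgeR adjusted p = 0.000202).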
